A study of Mus musculus with 6 samples.

How the data were processed

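Gene expression was measured on Illumina bead arrays, in which biotin-labelled RNA is hybridised to probes carried on beads. The 6 arrays held RNA of whole kidneys of mice at embryonic day 18.5, 3 from mutants and 3 from wild type controls. Groups and replicate numbers were taken from the sample titles. The descriptions of the 3 mutant samples all name mouse 1, whereas the titles number them 1 to 3 and the series' design text speaks of 3 mutant kidneys. The titles were followed, and p-values measure the spread between these samples.

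The deposited value table holds log2 intensities of 45281 probes for the 6 samples, already normalized by the authors. The normalization method, the software and any background correction are not given in the sources used here. The log base is not given either. The values run from 6.81 to 16.1 in every array, and on a natural or decimal log scale the upper end would lie far beyond the range of a scanner, so log2 was used. Each array has a median of 7.73, and at any rank the sorted values of the 6 arrays differ by at most 0.00737, as quantile normalization leaves them. The values are not centred by probe. An array's total brightness is therefore not kept in this table, and a change shared by most probes would have been removed from it.

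A second deposited table of signals holds 14 columns of values, 6 of them signals, named only by slide barcode and position. No label ties a position to a sample, so these columns were not used. The value table pairs no probe ID with a gene, and its probe IDs have no counterpart among the probe numbers of the signal table. Probes are therefore reported by ID, at most 2 in each direction, and genes, genomic positions, detection p-values and slides were not analysed here. The level of Rbpj, the targeted gene, and the gene lists fixed before the data were examined (Notch target genes, principal and intercalated cells and other kidney cell types) were not analysed for the same reason.

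The planned processing (neqc on signals with detection p-values, and 1 probe per gene) was replaced by a test of the deposited log2 values. As planned for data without detection p-values, the brighter part of the probes was tested, those with a mean over all 6 arrays above the median over probes. This kept 22640 probes, with mean values of at least 7.71. Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior, group as the only term), and p-values were adjusted by Benjamini-Hochberg over the 22640 probes with a threshold of 0.05. Fold values are 2 to the power of the log2 difference. Where background was not subtracted, such folds understate the change of dim probes. The precision is limited by the number of arrays.

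The named probes are the 2 with the largest rise and the 2 with the largest fall among those past the threshold whose 3 mutant values all lay on one side of the 3 wild type values. That rule, with more places, was fixed before the data were examined. The procedure was tested on simulated data with the real means and spreads of the 22640 probes, of which 200 were changed. It recovered 61 of 100 probes changed by 1.5-fold and 85 of 100 changed by 2-fold, all in the right direction, with 4 false calls among 150. The simulated noise was independent between probes, without differences shared across an array, and took the SDs estimated from the 6 arrays as true. The real data gave 23 calls, fewer than the 150 simulated ones, and the Benjamini-Hochberg adjustment is stricter where fewer probes change. These rates may therefore not carry over to the real arrays, where fewer changes of these sizes may be recovered.

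Replicate numbers are shared between the groups. The deviations from the group means of same-numbered samples correlated at -0.03, -0.09 and -0.07, so the numbers were not treated as pairs. No 2 arrays were identical. Alternatives were no filter on dim probes, the replicate number as a block, leaving out each sample, a mean-variance trend with robust estimation, array weights and other thresholds. The brightest 25% of probes and cyclic loess on the deposited values were added after the data had been seen.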

Results

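The data were 6 Illumina bead arrays of whole mouse kidneys at embryonic day 18.5, with 3 mutants and 3 wild type controls. The mutants carried 1 floxed and 1 null allele of Rbpj and the HoxB7Cre transgene. Rbpj is the DNA-binding protein through which Notch receptors act on transcription, and HoxB7Cre deletes floxed alleles in the ureteric bud and the collecting ducts that grow from it. The controls were littermates with both Rbpj alleles floxed and no Cre. The null allele was thus present in every cell of the mutant kidneys, whereas the Cre-dependent loss was directed to the collecting ducts, and the whole organ was measured. The sex of the embryos had not been determined. The comparison addressed which transcripts depend on Notch signalling in the developing collecting ducts.

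The 6 arrays were close to each other over the 22640 probes tested. Pearson correlations across probes, which are not independent replicates, were between 0.993 and 0.994 for the 3 pairs of mutants and between 0.993 and 0.994 for the 3 pairs of wild types. The 9 pairs of 1 mutant and 1 wild type had correlations between 0.992 and 0.994. The median SD over probes was 0.11 on the log2 scale in the mutants and 0.11 in the wild types (n = 3 each). The first principal component carried 25.4% of the variance and did not separate the groups. Mutant replicate 3 scored -3.89 on it and wild type replicate 3 scored -2.62, while the other mutants scored 11.9 and 16.4 and the other wild types -8.75 and -13.0. The second component carried 23.9% and set wild type replicate 3, at 22.4, apart from the other 5 arrays, which scored from -7.00 to 0.55. That array also had the lowest weight, 0.75, when limma estimated weights for the arrays.

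Between mutant and wild type kidneys, 23 of the 22640 probes changed (limma with Benjamini-Hochberg adjustment). Of these, 14 rose in the mutants and 9 fell. The probes that rose did so by 1.54-fold to 4.61-fold, with a median of 1.97-fold, and 6 of them rose by at least 2-fold. The probes that fell did so by 1.52-fold to 3.08-fold, with a median of 1.83-fold, and 2 of them fell by at least 2-fold. In all 23 the 3 mutant values lay on one side of the 3 wild type values. Calls at this threshold all but require that, so it is no added evidence. Over all tested probes the share with groups apart in this way was 11.3%, where chance gives 10%.

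**Figure D1:**
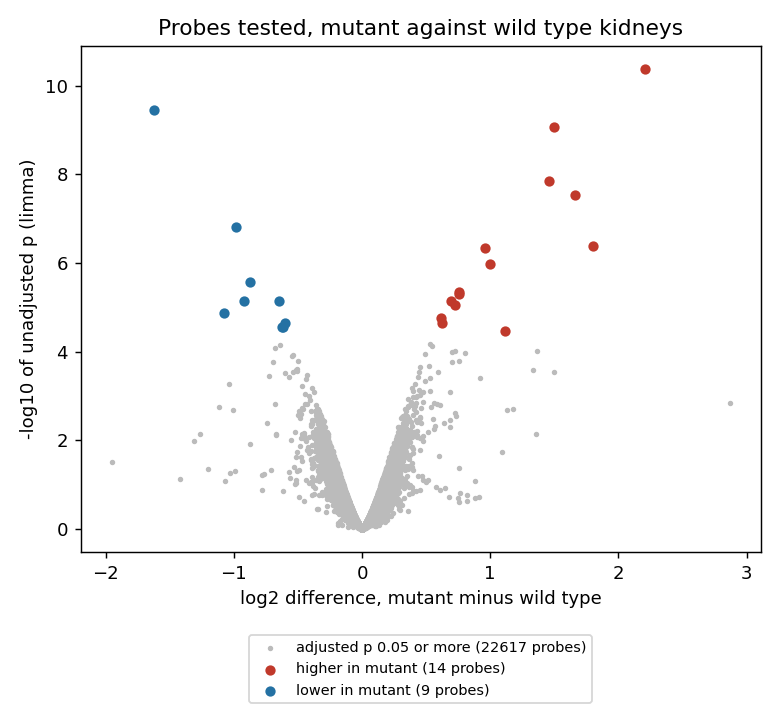
Each point is 1 of the 22640 tested probes, with the log2 difference of mutant minus wild type on the x axis and -log10 of the unadjusted limma p on the y axis. The 14 coloured probes on the right rose and the 9 on the left fell at an adjusted p under 0.05, and the others are grey.

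Among the changed probes, the largest rise was that of ILMN_2898944. Its normalized log2 intensity was 7.47 ± 0.099 (SD, n = 3) in wild type and 9.67 ± 0.091 (SD, n = 3) in mutant kidneys, a log2 difference of 2.21 with a standard error of 0.09 (limma adjusted p = 9.48e-07). On the deposited scale this is a 4.61-fold higher intensity. The wild type level lay below the array median of 7.73, and background and detection were not used here. The size of the change and its rank among the changed probes therefore hold for the deposited values only. The lowest mutant and the highest wild type value of ILMN_2898944 were 2.02 log2 units apart, and neither group spanned more than 0.20. Probe ILMN_3161626 rose from 8.19 ± 0.17 to 9.99 ± 0.43 (SD, n = 3 each), or 3.49-fold (limma adjusted p = 0.00129). Mutant replicate 1 had the highest value of that probe, 10.5, and the other mutants had 9.70 and 9.79.

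The largest fall among the changed probes was that of ILMN_3140091, from 9.96 ± 0.021 in wild type to 8.34 ± 0.049 in mutant kidneys (SD, n = 3 each). The log2 difference was -1.63 with a standard error of 0.08 (limma adjusted p = 4.04e-06), a 3.08-fold lower intensity. The groups were 1.55 log2 units apart at their nearest values, and neither spanned more than 0.10. Probe ILMN_2783873 fell from 9.55 ± 0.36 to 8.47 ± 0.076 (SD, n = 3 each), a 2.11-fold lower intensity (limma adjusted p = 0.0177). The wild types differed among themselves in this probe, from 9.16 in replicate 3 to 9.87 in replicate 2. Its call was lost when any of the 3 mutants or wild type replicate 1 was left out, with limma adjusted p-values up to 0.103. The log2 difference itself moved little in those 4 fits, from -1.03 to -1.11, against -1.08 with all samples. The value table pairs none of these probes with a gene.

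**Figure D2:**
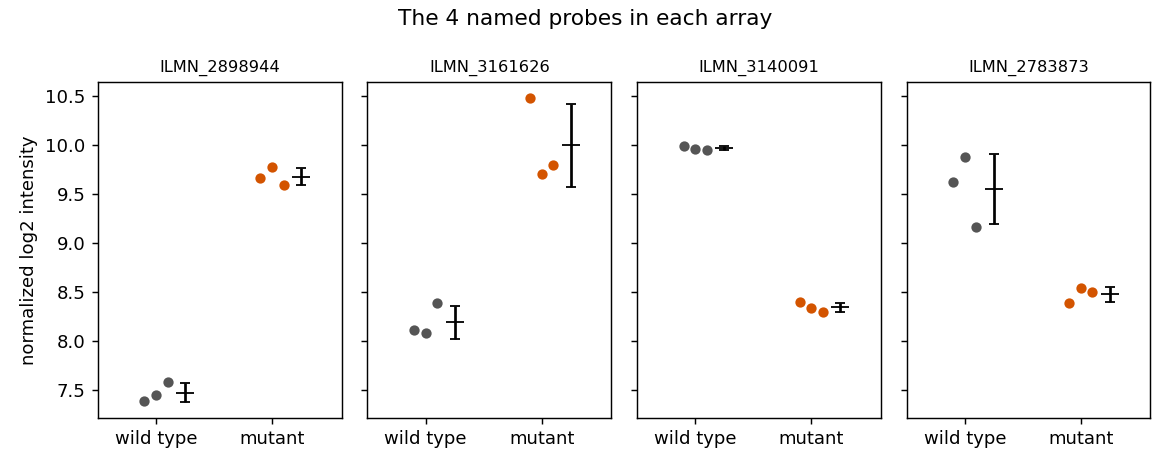
Normalized log2 intensity (y axis) of the 4 named probes in each of the 3 wild type (grey) and 3 mutant (orange) arrays, with the mean and SD of each group as the bar beside the points. The 3 mutant points lie above all wild type points for ILMN_2898944 and ILMN_3161626 and below them for ILMN_3140091 and ILMN_2783873.

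For most probes the data set a narrow bound on any difference in the deposited intensities. It is not a bound on the RNA. The tested means reach down to 7.71, and folds of dim probes are understated where background was not subtracted. A change shared by most probes would have been removed, and one in the collecting ducts alone is diluted in the whole organ. The half-width of the 95% confidence interval of the log2 difference had a median of 0.22 over the tested probes, which corresponds to 1.16-fold. For 97.8% of the probes the interval excluded a change of 1.5-fold or more in deposited intensity in either direction. Another 18 probes differed by at least 2-fold in their means without passing the threshold. In total 1399 probes had an unadjusted p under 0.05, where 1132 are expected by chance alone. That excess was not stable: leaving out 1 sample gave 934 to 1732 such probes, and the lowest count, without mutant replicate 1, lay below the number expected.

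The number of changed probes depended on single samples. Without mutant replicate 2 it was 11, and without wild type replicate 1 it was 14. Without wild type replicate 3, the array set apart on the second component, it was 34. Of the 23 probes, 10 passed in every one of the 6 fits that left out 1 sample, of which 7 rose and 3 fell.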

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

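The count of 23 changed probes stayed within 1.5 times under the block, the filter, the variance model, the array weights and the other thresholds, from 23 to 34. An added bound of at least 1.5-fold could not lower it, because the smallest change was 1.52-fold. With the replicate number as a block it was 23, of which 17 rose and 6 fell, and 18 of these were among the original 23. The block is not read as a pairing of the animals, because no label gives one and same-numbered samples did not deviate together. So few samples cannot exclude a pairing. The controls were littermates, but litter was not part of any model here. Without a filter on dim probes the count was 31, with array weights 31 and with a mean-variance trend and robust estimation 34. Leaving out 1 sample gave 11 to 34 probes, the highest without wild type replicate 3. The brightest 25% of probes, an alternative chosen after seeing the data, gave 8. Only 9 of the 23 probes were tested there, and 8 of these were called. Cyclic loess, also added later, gave 23, the same probes. It ran on values already normalized, so it hardly tests the normalization. Of 44 fits of 1 named probe under 1 alternative, 40 passed the threshold. None reversed in direction, but the named probes were chosen for groups that lie apart, so a reversal could hardly occur. The other 4 were those of ILMN_2783873 without a mutant or without wild type replicate 1. Alternatives that need the signals, detection p-values, slides or gene names were not run: quantile normalization without background correction, detection on all 6 arrays, the slide as a block, Xist as a covariate, other rules for the probes of a gene, and all list tests. The deposited value table, planned as an alternative, is the data tested here. The signal over background behind each value was not used here.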

Other observations

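All tests in this part were chosen after the values they rest on had been seen. The first pattern is the set of 23 changed probes. The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of the 10 splits, the real one, gave 23 probes, while the highest of the others gave 5. With 10 splits no share under 0.05 can be reached. The count at an unadjusted p under 0.05 was less distinctive: the real split had 1399 probes, and the split of wild type replicates 1 and 2 with mutant replicate 3 against the rest had 1945. The remaining splits had 630 to 1308.

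The mice had a mixed genetic background, so probes may differ between animals through sequence variants that have nothing to do with Notch. A variant with a large effect on hybridisation, carried alike on both chromosomes, would leave a probe at one of 2 separate levels. Where some animals of a group are heterozygous, or the effect is smaller, it would not, and such variants were not searched for. A probe was counted as having 2 levels when the largest gap between its 6 sorted values was at least 1 log2 unit and at least 3 times the wider range on either side of it. In all 43 probes met this, and 18 of them set a single array against the other 5. Another 4 set mutant replicate 1 and wild type replicate 2 apart from the remaining arrays, a grouping that cuts across the genotypes. The 2-level probes that followed mutant against wild type numbered 4, all among the 23 changed probes, against at most 2 in any other split of 3 and 3. They include ILMN_2898944 and ILMN_3140091, the largest rise and the largest fall among the changed probes. That is too few to settle whether unlinked variants contribute. A candidate explanation for these 4 is a variant near the Rbpj null allele or the Cre transgene, carried along with the genotype. The null allele is on 1 chromosome, so a variant near it would be heterozygous in all 3 mutants. That could still part the groups. Loss of hybridisation of 1 copy of 2 would lower the RNA detected by about 2-fold at most, and ILMN_3140091 fell by 3.08-fold. That does not exclude a linked variant for this probe. The bound covers neither variants near the Cre transgene nor those that alter expression, and the fold is one of deposited values. With probe positions not used here, a linked variant cannot be told apart from an effect of lost Rbpj. Most of the other changed probes differed by less than 1 log2 unit in their means and could not have met the criterion, so variants stay open for them too. A biological effect of the genotype stays open and untested for all 23.

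The second pattern is that the descriptions of the 3 mutant samples name a single mouse. If 1 mouse had been measured 3 times, probes would hardly differ strongly between those arrays. In the mutants 17 tested probes had a range of at least 2 log2 units, against 20 in the wild types, whose descriptions name separate mice, and the median SD over probes of the mutants was 0.978 times that of the wild types. These values argue against 1 mutant mouse measured 3 times only if repeats of 1 mouse differ less than separate mice do. No array pair known to be technical repeats was there to show that. The 2-level probes bear on it more directly. Mutant replicate 1 parted from the other mutants at a level shared only with wild type replicate 2 in 4 probes. With wild type replicate 3, mutant replicate 3 did so in 3 and mutant replicate 2 in 2. Repeats of 1 mouse would hardly part in this way, so these few probes argue against that reading. Single mutants stood alone in 1, 2 and 0 probes, against 0, 9 and 6 for single wild types. The number of mutant mice is not shown.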
